A study of Homo sapiens with 9 samples.

How the data were processed

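RNA sequencing was done on 9 libraries of a cell line labelled Huh7, a line derived from a human hepatocellular carcinoma and grown, per the labels' protocols, in DMEM. The labels name 3 groups of 3 libraries each: control, and OPA1 knock-down sets called N_28 and N_30. The knock-down was made with lentivirus per the labels' protocols, which state the same treatment text for control libraries. The labels do not say what N_28 and N_30 stand for, and they are used here as the names of the knock-down sets. Libraries were made from total RNA by standard Illumina protocols per the labels. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

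The deposited table holds raw read counts per gene, whole numbers under human Ensembl gene identifiers, for 60448 rows and 9 columns. A normalization by the authors is not given in the sources used here. The submitters' processing notes name the mouse build mm8, while the rows carry human identifiers. The aligner, the counting tool, the annotation release and whether counting used strand are not given in the sources used here. Reads of overlapping genes on opposite strands and of near-identical gene copies are therefore uncertain in their assignment. Gene symbols were taken from a gene name table for 56434 rows and from GENCODE release 29 for 434 more, which left 3580 rows without a name. Coordinates are those of the identifiers in GENCODE release 29, on the human build GRCh38.

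Total counts per library ran from 16476389 to 22863328. Of the 60448 rows, 30527 had no reads in any library. After edgeR's expression filter with a minimum count of 10, 15019 genes were tested, 101 of them without a symbol. A count of 3 in the smallest library equals 0.182 CPM (counts scaled to the size of the library), and this floor covers counting error only. The common biological coefficient of variation was 0.0783. Pairs of libraries of one group differed by a chi-square of 3.58 to 12.4 per gene, above the value of about 1 that sampling noise gives, so no library was treated as a copy of another. Libraries of the same number in control and N_30 deviated together from their group means in all 3 pairs (correlations of 0.122, 0.169 and 0.306), so their numbers are read as pairing them, from the data and not the labels, while pairs with N_28 ran from -0.0588 to 0.235. That reading was made after the calls with the block were known, so values without the block stay as the first ones given.

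Counts were scaled by trimmed mean of M values (TMM) and fitted in edgeR 4.0.16 (R 4.3.3) with a quasi-likelihood model of all 9 libraries, with a term for each of the 3 groups, which thus share an estimate of the spread. The comparisons were N_28 against control, N_30 against control, the mean of both knock-downs against control, and N_30 against N_28. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2 scale with a standard error (SE) derived from the fold change and the test statistic. Levels are CPM on TMM-scaled library sizes, as mean ± SD over 3 libraries.

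The groups, the comparisons, the tests, 38 gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with the correlation estimated from the libraries. For each list, calls were also counted with the p-values adjusted over the list alone. Named genes were OPA1, the 10 largest rises and 10 largest falls called in both knock-downs in the same direction, the 5 largest rises and 5 largest falls of each knock-down, and the 5 highest and 5 lowest differences between the knock-downs. These had a mean of at least 5 CPM and no overlap between the libraries compared. From each list, up to 4 members with the lowest adjusted p in the mean of both knock-downs were named, and up to 2 well-known members that did not pass. Genes called in both were ranked by the smaller of their changes in size. Other members that passed in a list, the liver and epithelial genes given by level, and genes called in opposite directions were named after their values were seen.

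Agreement between the knock-downs was set against 40 simulations in which all 9 libraries had no effect but shared the 3 controls, and against fold changes computed with disjoint control libraries, also with each knock-down library set against the control of its own number so that no library was used in both. The 22 autosomes were compared as gene sets by the same camera test, with genes of a mean of at least 5 CPM. The chromosome test, its expression bound, its stretches and the restriction to autosomes were chosen after shifts of chromosome medians had been seen in the same data. Each autosome was also cut into stretches of about 50 such genes, 199 in all.

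Alternatives were other scalings (DESeq2 size factors and upper quartile), no filter, a filter at a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, fits of only the groups compared, stricter thresholds, other prior counts, the replicate number as a block, and leaving out each library in turn. Counts of opposite calls, disjoint controls, disjoint libraries matched by number, lists differing between the knock-downs and all chromosome results were added after seeing the data. The scripts were tested on simulated data for N_28 against control with 15019 genes: 35 of 50 genes changed 1.5-fold, 39 of 50 changed 2-fold, 48 of 50 changed 3-fold and 46 of 50 changed 4-fold were recovered, with 9 false calls. With the genes of 1 chromosome raised in simulated libraries, the chromosome test called that chromosome. That simulated rise was larger than the chromosome medians found here, and the simulated genes varied independently. Shifts of the size found here were thus not tried. Figures were drawn with matplotlib.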

Results

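The data are gene counts from 9 RNA sequencing libraries of cells labelled Huh7, with 3 control libraries, 3 of the OPA1 knock-down set N_28 and 3 of the knock-down set N_30. OPA1 is a dynamin-like GTPase of the inner mitochondrial membrane that acts in membrane fusion and keeps the cristae in shape. The depth was 19510555 to 22164035 counts in control, 18316731 to 22863328 in N_28 and 16476389 to 22400589 in N_30 libraries. The design asks which transcripts change when OPA1 is lowered, and the knock-down sets allow that question to be put to each set in turn.

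The OPA1 transcript was lower in every knock-down library than in every control library. OPA1 (ENSG00000198836, chromosome 3, 193593144 to 193697823, plus strand, GENCODE release 29 on GRCh38) stood at 88.7 ± 5.28 CPM (SD, n = 3) in control libraries. In N_28 it was 55.6 ± 2.25 CPM (n = 3), which is 62.6% of control, and in N_30 it was 64.5 ± 1.30 CPM (n = 3), or 72.7% of control. The log2 fold change was -0.68 (SE 0.06, adjusted p = 1.38e-05) in N_28 and -0.46 (SE 0.06, adjusted p = 0.00221) in N_30 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. N_30 lay above N_28 by 0.21 on the log2 scale (adjusted p = 0.0265, same test). An antisense gene, OPA1-AS1, lies inside OPA1, and its reads cannot be told apart from those of OPA1 without strand.

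**Figure D1:**
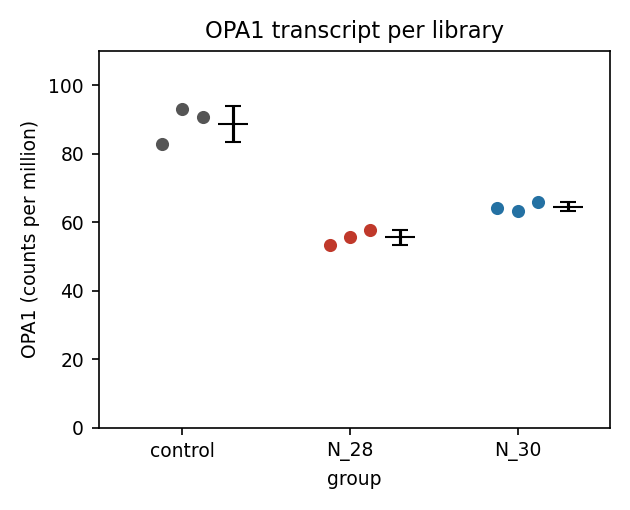
OPA1 level in CPM (vertical axis) in each library of the 3 groups (horizontal axis), one point per library, with the mean and SD of 3 libraries as a bar to the right. Control libraries lie between 82.8 and 92.9 CPM, N_28 between 53.3 and 57.8 CPM and N_30 between 63.3 and 65.9 CPM.

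Several marker genes of the mature liver were close to undetected in all 9 libraries labelled Huh7, controls included, while other liver genes were detected. Albumin (ALB) had 0 to 10 counts per library, the apolipoprotein gene APOA1 at most 4, and APOB had 0 counts in every library. Alpha-fetoprotein (AFP), a marker of fetal liver and liver cancer, ran from 0.578 to 1.31 CPM. The liver transcription factor HNF4A reached at most 0.181 CPM. Of 54 secreted hepatocyte proteins, 13 had a control mean of at least 1 CPM and 1 of at least 100 CPM, with a median of 0.0554 CPM. Of 51 genes of hepatocyte metabolism and detoxification these were 18 and 2, with a median of 0.0619 CPM. Complement C3 stood at 28.3 ± 4.14 CPM and the bile acid enzyme BAAT at 16.6 ± 1.93 CPM in control (n = 3). The mesenchymal filament VIM stood at 1493 ± 66.4 CPM in control (n = 3), N-cadherin (CDH2) at 148 ± 7.58 CPM, and the epithelial cadherin CDH1 at 1.72 ± 0.668 CPM. The keratin KRT8 had 411 ± 33.6 CPM and the endoderm factor FOXA2 65.9 ± 3.18 CPM.

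**Figure D2:**
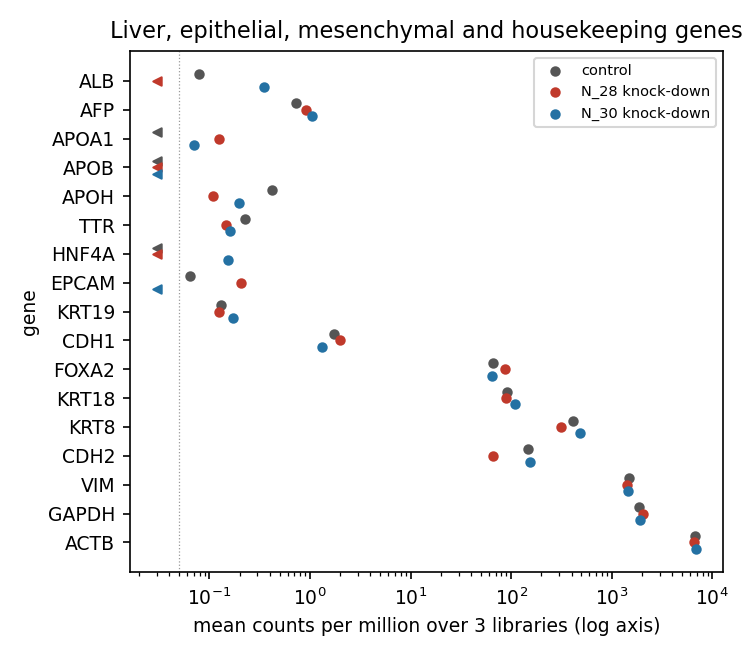
Mean level in CPM over 3 libraries (log axis) of 17 genes in control, N_28 and N_30, one point per group, with group means under 0.05 CPM drawn as triangles at the left edge. Liver genes from ALB to HNF4A lie near or below 1 CPM in every group, while VIM, GAPDH and ACTB lie above 1000 CPM.

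In N_28, 675 genes rose and 863 fell against control, out of 15019 tested. The chloride channel gene ANO1 rose from 7.48 ± 0.492 to 31.1 ± 4.22 CPM (n = 3 each), a log2 fold change of 2.06. The cytokine subunit EBI3 rose by 1.58, the matricellular gene TINAGL1 by 1.52, the small proteoglycan biglycan (BGN) by 1.48 and the non-muscle myosin MYH14 by 1.40 on the log2 scale. The succinate receptor SUCNR1 fell from 9.22 ± 1.80 to 0.529 ± 0.367 CPM, a log2 fold change of -4.17. EVA1A had a log2 fold change of -2.92, the transcription factor musculin (MSC) of -2.66, the adhesion receptor ADGRL4 of -2.05 and TMEM158 of -1.86. Adjusted p-values of these 10 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were at most 0.000555 (TINAGL1).

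Few genes of mitochondrial structure were called in N_28. Of 24 tested genes of mitochondrial fusion and fission, 1 rose, the actin regulator INF2 (0.33), and 23 did not pass; adjusted over the list alone, 1 rose as well. Among 12 genes of MICOS, the complex that holds cristae junctions, and of 35 subunits of respiratory complex I, 0 passed, and 0 passed adjusted over the list alone. Of 40 subunits of complexes II to V, COX7C (0.31) and ATP5F1D (0.26) rose, and 1 rose adjusted over the list alone. None of the 13 mitochondrially encoded mRNAs passed, with MT-CO1 at -0.09 and MT-CO2 at -0.16, and 0 passed adjusted over the list alone. In the mitochondrial ribosome, 1 of 74 members rose (MRPS6, 0.31) and 2 fell (MRPS16, -0.43, and MRPL43, -0.20), with 0 and 1 adjusted over the list alone. Of 21 mitochondrial chaperones and proteases, 0 passed under either adjustment. Calls of list members were not counted with the replicate block, so smaller changes may be missed.

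Single members of stress and metabolic lists passed in N_28, and camera called none of these lists. In the integrated stress response, PPP1R15A (0.76) and SLC7A1 (0.31) rose among 34 tested genes, and 2 rose adjusted over the list alone, while DDIT3 (0.51) did not pass. Of 33 genes of the NRF2 and glutathione list, 5 rose and 2 fell (6 and 3 adjusted over the list alone). The quinone reductase NQO1 rose by 1.35, from 153 ± 26.6 to 389 ± 61.1 CPM, and GPX1 by 0.29, while AKR1C3, which has near-identical paralogs, fell by 0.51. In the glycolysis list the lactate exporter SLC16A3 rose by 1.03 and the glucose transporter SLC2A1 fell by 0.44, out of 24 (1 rose and 2 fell adjusted over the list alone). SLC16A3 is low, and went from 2.97 ± 0.217 to 6.10 ± 0.289 CPM. Of 22 hypoxia response genes, 1 rose and 3 fell (2 and 4 adjusted over the list alone), with ADM at 0.62 and BHLHE40 at -1.08. In the unfolded protein response of the endoplasmic reticulum, 3 of 26 rose and 1 fell (4 and 2 adjusted over the list alone), led by HERPUD1 at 0.56. Among 47 genes of G1/S and DNA replication, FEN1 (-0.68), RFC3 (-0.42) and GINS1 (-0.29) fell and CDT1 (0.23) rose, with 3 and 1 adjusted over the list alone.

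Of the 16 tested hepatocyte secreted proteins, 9 fell and 0 rose, also adjusted over the list alone, among them fibrinogen alpha (FGA, -1.89) and the complement regulator C4BPA (-2.58). Most of these are low, and transferrin (TF) went from 4.01 ± 1.19 to 0.446 ± 0.334 CPM. This was the 1 of 37 tested lists that camera called in N_28 (lower, adjusted p = 0.000548), and the call was lost with adjusted p = 0.997 with an estimated correlation. It was also lost with a filter at a mean CPM of at least 5, under which 0 lists were called in N_28. Of 38 mesenchymal and matrix genes, 5 rose and 6 fell (7 and 6 adjusted over the list alone), with CDH2 at -1.15 and the urokinase receptor PLAUR at 0.89. Of 31 lysosomal genes, 1 rose and 5 fell, among them the cathepsins CTSZ (-0.28), CTSB (-0.24), CTSA (-0.45) and CTSD (-0.37), with the same counts of 1 and 5 adjusted over the list alone. Of 24 immediate early genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone), with the factor KLF2 at 1.43 and JUNB at -1.04. KLF2 is low as well, and went from 2.41 ± 0.288 to 6.52 ± 0.551 CPM. The total of 1538 calls fell to 967 without N_28 replicate 1.

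**Figure D3:**
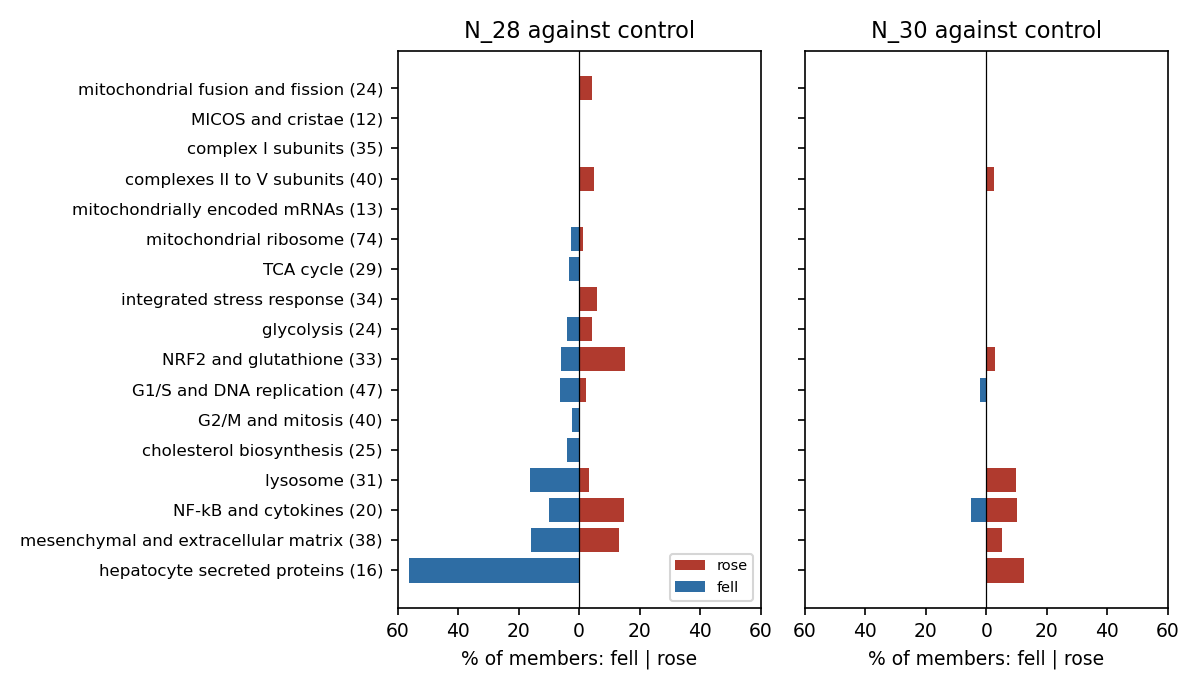
Share of the tested members of 17 gene lists, in percent (horizontal axis), that rose (right) or fell (left) against control in N_28 and in N_30, with the number of tested members in parentheses. In N_28, 9 of 16 hepatocyte secreted proteins fell, while in N_30 2 of them rose.

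In N_30, 69 genes rose and 61 fell against control among the same 15019. Complement C3 rose most, from 28.3 ± 4.14 to 99.4 ± 17.8 CPM (n = 3 each), a log2 fold change of 1.81. IGFBP1, a secreted binder of insulin-like growth factors, rose by 1.52, DNER by 1.38, the EGF receptor ligand TGFA by 1.25 and IGFN1 by 1.07 on the log2 scale. The bile acid conjugating enzyme BAAT fell from 16.6 ± 1.93 to 7.10 ± 1.31 CPM, a log2 fold change of -1.24. The secreted Wnt antagonist SFRP1 had a log2 fold change of -1.17, the decoy receptor IL13RA2 of -1.13, SH3TC2 of -1.08 and the BMP family gene GDF7 of -1.07. The highest adjusted p of these 10 genes was 0.0324 (DNER), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

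Among the mitochondrial lists, COX7C (0.34) was the 1 gene to rise in N_30, and 0 members of fusion and fission, MICOS, complex I, the mitochondrial ribosome, the TCA cycle, the chaperone list and the mitochondrially encoded mRNAs passed. The same held adjusted over the list alone, with 1 of 40 members of complexes II to V and 0 of the other lists. These counts come from the fit without the replicate block. The block raised the calls in N_30 from 130 to 424, and calls of list members were not counted with it, so smaller changes may be missed. Of 31 lysosomal genes, 3 rose, among them CTSD (0.46) and CTSA (0.34), and 0 fell (5 and 0 adjusted over the list alone). In the hepatocyte secreted list 2 of 16 rose, among them C3, and 4 rose adjusted over the list alone. In the NF-kB and cytokine list of 20 genes, the adhesion molecule ICAM1 (0.78) and TNFAIP2 (0.35) rose and the chemokine CXCL6 (-0.54) fell, with 5 and 1 adjusted over the list alone. Collagen COL5A1 (0.76) and TGFBI (0.50) rose among 38 mesenchymal and matrix genes (6 adjusted over the list alone). Of 33 NRF2 and glutathione genes the ferritin heavy chain FTH1 (0.38), which has many pseudogenes, rose, and 1 rose adjusted over the list alone. In G1/S and DNA replication GINS4 (-0.44) fell, the 1 of 47 members under both adjustments. Of 34 integrated stress response genes 0 passed, with DDIT3 at 0.43, and 1 rose and 1 fell adjusted over the list alone.

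Camera called 11 of 37 lists in N_30, 9 higher and 2 lower, by small shifts of many members. Leaving out 1 library at a time gave 6 to 14 called lists. The lysosome list was higher in 26 of 31 members (median log2 fold change 0.12), NF-kB and cytokines in 17 of 20 (0.38), cytosolic ribosomal proteins in 61 of 75 (0.05) and complexes II to V in 31 of 40 (0.05). Ribosomal protein genes held 4.48, 4.78 and 4.88% of counts in N_30 libraries 1, 2 and 3. In control libraries 1, 2 and 3 this share was 4.48, 4.65 and 4.65%. The other lists called higher were the mitochondrial ribosome, the unfolded protein response, NRF2 and glutathione, hepatocyte secreted proteins, and mesenchymal and matrix genes. G1/S and DNA replication and cholesterol synthesis were lower, each with 2 members above 0. Adjusted p-values ran from 6.82e-05 to 0.0390 with the preset correlation and from adjusted p = 0.682 to adjusted p = 0.791 with an estimated correlation, so 0 of the 11 calls held with it. The 130 gene calls fell to 58 without N_30 replicate 2, to 71 without N_30 replicate 1 and to 78 without control replicate 3, and they were 267 by DESeq2, 523 with no filter on low counts and 424 with the replicate number as a block. DNER, SH3TC2, GDF7 and IGFBP1 each missed the threshold in N_30 under 2 or more alternatives.

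Genes called in both knock-downs in the same direction numbered 23, 14 higher and 9 lower, and OPA1 was among them. IGFBP1 (1.38 in N_28 and 1.52 in N_30), IGFN1 (0.96 and 1.07), BGN (1.48 and 0.89), PCDH7 (0.58 and 0.84), TBC1D2 (0.62 and 0.73) and TULP3 (0.84 and 0.57) rose in both. The cell surface proteoglycan SDC4 (0.58 and 0.57), MGAT4B (0.56 and 0.48), PDZK1IP1 (0.50 and 0.53) and RABL6 (0.39 and 0.43) rose as well. BAAT (-1.22 and -1.24), IL13RA2 (-1.82 and -1.13), ADGRL4 (-2.05 and -0.86), PAX9 (-0.69 and -0.42), CXCL6 (-0.38 and -0.54) and RASSF2 (-0.34 and -0.26) fell in both. Of 13 alternatives, the N_30 call was lost under 9 for RASSF2, 8 for PDZK1IP1, 4 for TBC1D2, 2 for PAX9 and 2 for IGFBP1. Insulin-like growth factor IGF2 (-2.92 and -2.16) fell from a low level of 1.76 ± 0.153 CPM in control, in a region where it overlaps a read-through gene with INS. In the test of the mean of both knock-downs against control, 80 genes rose and 188 fell, and camera called 1 list, the unfolded protein response (higher, adjusted p = 0.0250), which had adjusted p = 0.912 with an estimated correlation. That gene count was 134 without control replicate 1, 172 without control replicate 3, 168 without N_28 replicate 1, 408 by DESeq2 and 705 with no filter. The 23 shared calls were 13 without N_30 replicate 2, 47 by DESeq2, 96 with no filter and 74 with the replicate block, which gave 616 genes and 6 lists in the mean of both.

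With no bound on the size of the change, more genes were called in opposite directions than in the same direction, 55 against 23. Of the 55, 28 were higher in N_28 and lower in N_30 and 27 the reverse, where independent lists would share 6.71 in opposite and 6.61 in the same directions. C3 (-1.08 in N_28 and 1.81 in N_30), NNMT (-1.40 and 0.84) and TMEM158 (-1.86 and 0.63) fell in N_28 and rose in N_30. SFRP1 (0.75 and -1.17), SH3TC2 (0.91 and -1.08), JAM3 (0.80 and -1.03), MCAM (0.89 and -0.81), DLK1 (0.79 and -0.87) and OAS1 (0.78 and -0.79) went the other way. Across all genes, which are not independent replicates, the fold changes of the knock-downs had a Pearson correlation of 0.0337 and a Spearman correlation of 0.0491. The Pearson correlation was -0.0882 over genes with a mean of at least 5 CPM and -0.00633 with a prior count of 10. With no effect at all, the shared controls alone gave 0.496 ± 0.0182 (Pearson) and 0.453 (Spearman) in 40 simulations, with 0.05 calls in the same direction and 0 in opposite directions on average. Almost no gene is called where no effect is simulated, so these simulated counts of calls are no measure for the 55 and 23. The covariance was 0.00327 against a simulated 0.0195 ± 0.00107, a difference of -0.0162. The 3 controls cannot be split into parts of at least 2 libraries, so part of the shared calls may come from the shared controls. The 55 opposite calls were 24 without N_30 replicate 2, 28 without N_30 replicate 1, 27 without control replicate 3, 32 with only the groups compared, 96 by DESeq2, 170 with no filter and 156 with the replicate block. At an adjusted p under 0.01, 19 genes were called in opposite directions and 14 in the same direction. With a log2 fold change of at least 1 the order turned, with 2 in opposite directions and 5 in the same direction.

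**Figure D4:**
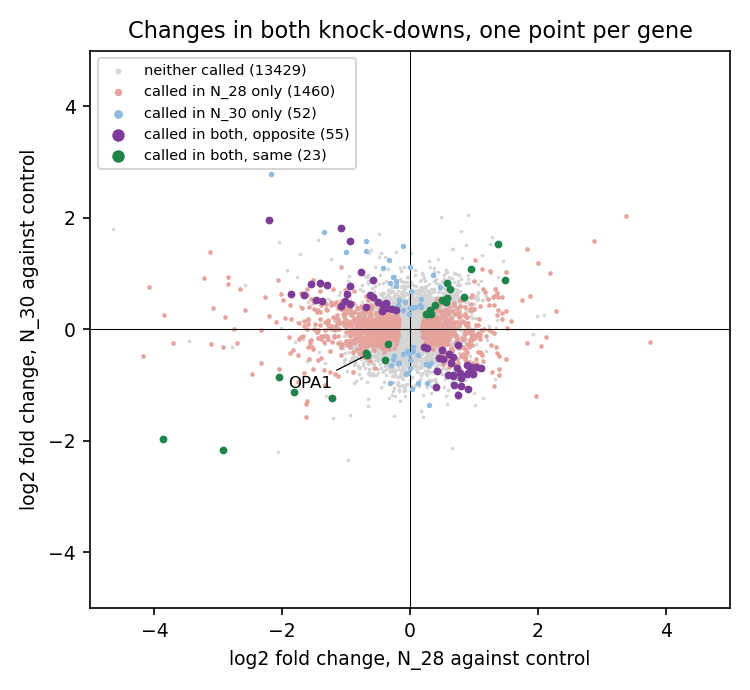
Log2 fold change of each tested gene against control in N_28 (horizontal axis) and N_30 (vertical axis), coloured by whether it was called in neither, in 1 or in both, with 4 genes outside the axes. The 55 genes called in opposite directions lie in the upper left and lower right, the 23 called in the same direction in the other corners, and OPA1 is lower in both.

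The largest set of differences lay between the knock-downs themselves, with 1409 genes higher and 1346 lower in N_30 than in N_28. SUCNR1 was higher in N_30 by 3.70 on the log2 scale, MSC by 3.38, C3 by 2.89, EVA1A by 2.60 and TMEM158 by 2.50. ANO1 was lower in N_30 (-2.35), as were MYH14 (-2.11), SH3TC2 (-1.99), SFRP1 (-1.92) and JAM3 (-1.83). Adjusted p-values of these 10 genes were at most 5.15e-05 (SUCNR1) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 31 lysosomal genes, 13 were higher and 1 lower in N_30 (15 and 1 adjusted over the list alone), and of 16 hepatocyte secreted proteins 10 were higher and 0 lower under both adjustments. Camera called these 2 lists, with adjusted p = 0.000108 and adjusted p = 2.54e-06, and both had adjusted p = 0.939 with an estimated correlation. Of the 2755 genes, 1481 were called in neither knock-down against control. On the first principal component, with 38.4% of the variance, N_28 libraries averaged 28.8 ± 1.24, controls -8.09 ± 2.44 and N_30 libraries -20.7 ± 2.16 (SD, n = 3 each). On the second component, with 13.9% of the variance, library 3 of each group lay at 10.9 to 19.1 and the other 6 libraries at 2.85 or below, a difference between libraries of one group.

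In an analysis added after the gene values had been seen, genes of whole chromosomes and of long chromosome stretches shifted together, most of them in opposite directions in the knock-downs. The median log2 fold change of 166 genes on chromosome 13 was 0.17 in N_28 and -0.08 in N_30, and that of 253 genes on chromosome 22 was -0.12 in N_28 and 0.06 in N_30. On chromosome 13, 33 genes rose and 5 fell in N_28, and 79 of the 83 genes called between the knock-downs were lower in N_30. On chromosome 22, 4 rose and 35 fell in N_28, and 83 of 94 were higher in N_30. On chromosome 6 the 5 stretches from 291630 to 44246166 had medians of 0.11 to 0.15 in N_28 and -0.08 to -0.05 in N_30, and the 4 stretches from 80003887 onward lay between -0.05 and 0.00 in N_28 and between 0.01 and 0.06 in N_30. On chromosome 19 the 7 stretches from 34359480 onward lay between 0.11 and 0.14 in N_28, and the 6 stretches up to 19033575 lay between -0.05 and 0.01. With the 22 autosomes as gene sets, camera called 10 in N_28, 7 in N_30 and 11 between the knock-downs at an adjusted p under 0.05, and 6, 2 and 7 held with an estimated correlation. Those called between the knock-downs with an estimated correlation were chromosomes 6, 9, 13, 14, 15, 20 and 22, with adjusted p from 0.00466 to 0.0495. Of the 12 chromosomes called in N_28 or N_30, 10 had medians of opposite sign, while chromosome 8 was lower in both (-0.03 in N_28, not passing, and -0.04 in N_30) and chromosome 7 was not lower in either (0.00, not passing, and 0.03). The calls of N_30 against control fell from 7 to 3 with all tested genes in place of those with a mean of at least 5 CPM.

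**Figure D5:**
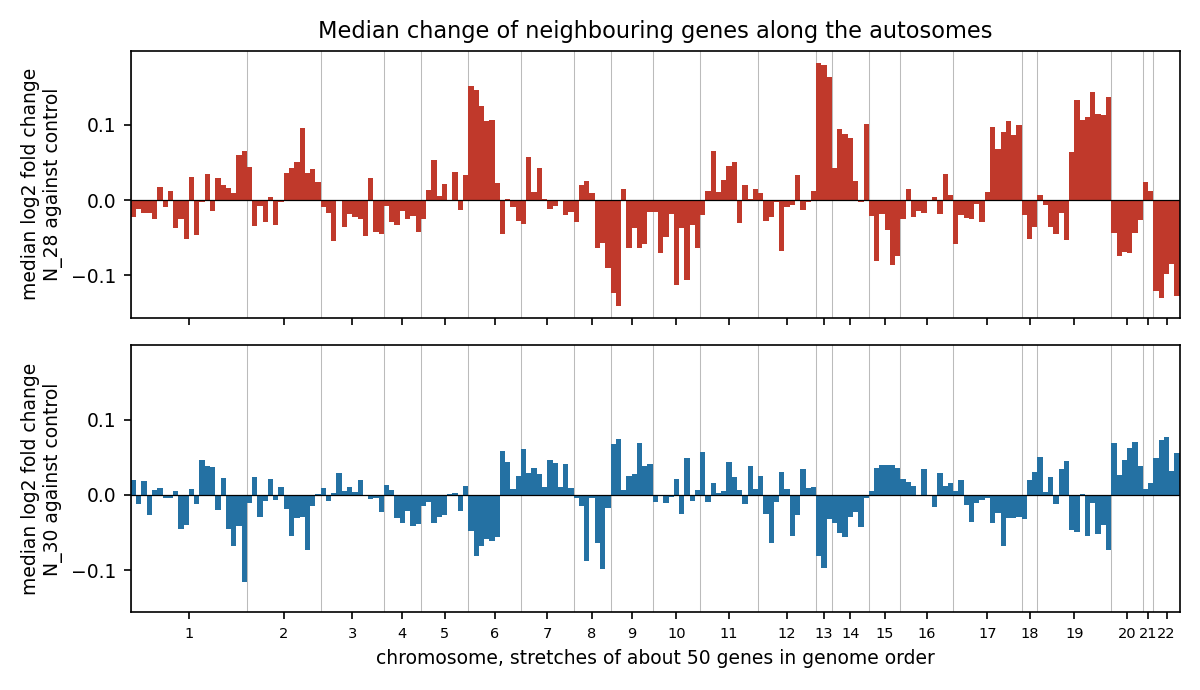
Median log2 fold change against control (vertical axes) of 199 stretches of about 50 neighbouring genes each, in genome order along the 22 autosomes (horizontal axis), in N_28 (upper panel) and N_30 (lower panel). Chromosome 13 and the first part of chromosome 6 lie above 0 in N_28 and below 0 in N_30, and chromosome 22 the reverse.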

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

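Of the tests given here, those on the smaller knock-down, the shared controls, libraries matched by number, single construct or culture effects, the dosage of chromosome stretches and all tests of the chromosome shifts were chosen after the results had been seen. Groups of 3 libraries are too small for a test of single outlying libraries. All results listed were picked out because the test of N_30 against N_28 found a difference between the knock-down sets.

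The number of genes that differed between N_30 and N_28 was 2755. OPA1 was higher in N_30 than in N_28 by 0.21 on the log2 scale. The other genes higher in N_30 were SUCNR1 (3.70), MSC (3.38), C3 (2.89), EVA1A (2.60), TMEM158 (2.50), DNER (2.39), TGFA (1.58), ADGRL4 (1.19), IL13RA2 (0.69) and PAX9 (0.27). Lower in N_30 were ANO1 (-2.35), MYH14 (-2.11), SH3TC2 (-1.99), SFRP1 (-1.92), JAM3 (-1.83), TINAGL1 (-1.50), EBI3 (-1.44), GDF7 (-1.10), BGN (-0.59) and TULP3 (-0.27). Camera called the lysosome list (adjusted p = 0.000108) and the hepatocyte secreted list (adjusted p = 2.54e-06) higher in N_30 than in N_28, and neither held with an estimated correlation (adjusted p = 0.939 for both).

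Beside 23 genes called in the same direction, 55 were called in opposite directions in the knock-downs, which a weaker OPA1 knock-down in N_30 does not account for. Over the 1538 N_28 calls the slope of N_30 on N_28 fold changes was -0.0116, against a ratio of 0.682 for OPA1 itself. The SE of that slope, 0.0195, is over resampled genes, which are not independent, and these genes were chosen for their N_28 change. Shared controls push the fold changes together, and with disjoint controls the mean covariance was -0.0173, and with disjoint libraries matched by number, in which an effect shared by libraries of one number cancels, it was -0.00980, below 0 for each of the 6 choices in both. GC content and transcript length accounted for a share of 0.00314 of the variance of the differences between the knock-downs. They are thus not the whole cause. With the median of its stretch taken from each gene, the mean correlation over genes was -0.191 with disjoint controls and -0.144 with matched libraries (-0.234 to -0.0682). An equal shift of all genes of a stretch is thus not the whole cause either. Genes may follow dosage in unlike degree, and a copy change may end inside a stretch, so direct dosage is not excluded. A gain or loss of chromosome segments in one culture stays open: a bound of 0.3 for the median of 50 neighbouring genes, set before that test, was met narrowly by a shift of 0.304 in size on chromosome 19, lower in N_30 (0.186 at most in 20 shuffled gene orders), though 43 of those 50 were zinc finger genes that may share regulation, a point seen only after the result, and the most shifted window elsewhere (chromosome 13, also lower in N_30) was at -0.29. Effects of a single construct and of a single transduced culture, with 55 opposite calls, cannot be told apart, because each set has 1 label in this design.

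Genes of whole chromosomes shifted together, and GC content and length do not account for it, since the chromosome medians kept 99.7% of their size with both taken out. A change in the mix of cells with different chromosome content is a candidate explanation: a control culture that holds both kinds of cell would lie between sets enriched for one or the other, and stretch medians of N_28 and N_30 had a mean correlation of -0.608 with disjoint controls (-0.735 to -0.542), while the lowest of 1000 shuffled gene orders for each of the 6 choices of controls was -0.417. With matched libraries that mean was -0.573 (-0.736 to -0.418), against a lowest shuffled value of -0.387, and chromosome 8, lower in both knock-downs, is an exception to the opposite shifts. All 8 stretches of chromosomes 13 and 22 moved the way of their chromosome, which regulation of whole chromosomes with no change in copy number could also give, and without DNA measurements these cannot be told apart. This is a hypothesis: chromosome medians were looked at first, the gene set, stretches and test were then chosen on the same data in the course of trying 6 explanations of the opposite changes, and an effect of OPA1 on chromosome content stays untested.

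With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 1538 genes in N_28 and the highest other split 0, and for N_30 these were 130 and 7, and between the knock-downs 2755 and 0, with 1 of 10 splits as large as the real one in each. For N_30, the 3 other splits that part all 3 same-number pairs called 0 genes, and the split with 7 keeps pairs together. For the 6 knock-down libraries taken as one group against the 3 controls, 8 genes were called, and 4 of the 84 splits gave as many, the real one included. That share is just under 0.05, but the other 3 follow structure of the libraries, so the rank of the real split says little about chance. They set apart the N_28 libraries (2423 genes, the highest), the N_30 libraries (106) and the libraries numbered 3 (70). With the replicate number as a block, the mean of both knock-downs against control had 616 calls, against 268 without it.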

How the results depend on the processing

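None of the genes named by rank (OPA1 and the largest changes) turned direction under the 13 alternatives run for each, and 719 of 754 such values stayed on the same side of the threshold; list members and genes named after their values were seen were not rerun. The 35 lost calls were of TBC1D2, PDZK1IP1, PAX9, RASSF2, DNER, SH3TC2, GDF7 and IGFBP1 in N_30 (9 of 13 alternatives for RASSF2 and 8 for PDZK1IP1) and of TBC1D2 in N_28, while OPA1 held throughout. Where a value below moved, the cause was not tested. With no filter, calls were 523 in N_30, 705 in the mean of both, 96 in the same and 170 in opposite directions. DESeq2 gave 267, 408, 47 and 96 for these, and fits of only the groups compared gave 32 opposite calls. At an adjusted p under 0.01 there were 794 calls in N_28, 47 in N_30, 96 in the mean, 1432 between the knock-downs, 14 in the same and 19 in opposite directions. With a log2 fold change of at least 1 these were 242, 26, 33, 462, 5 and 2, so calls in the same direction then outnumbered opposite ones. Upper quartile scaling gave 86 higher and 56 lower in N_30, against 69 and 61. Leaving out 1 library at a time gave 967 to 1712 calls in N_28, 58 to 180 in N_30, 134 to 322 in the mean, 1850 to 2919 between the knock-downs, 13 to 31 in the same and 24 to 67 in opposite directions. Lists called then ranged from 1 to 3 in N_28, 6 to 14 in N_30, 0 to 8 in the mean and 2 to 5 between the knock-downs. With an estimated correlation, 0 lists were called in each of the 4 comparisons. With a mean CPM of at least 5, 0 lists were called in N_28 and 3 in the mean. The correlation of fold changes was -0.0882 with a mean CPM of at least 5 and -0.00633 with a prior count of 10, against 0.0337. The covariance was 0.00327 for edgeR fold changes, -0.0173 with disjoint controls and -0.00980 with disjoint libraries matched by number, alternatives chosen after seeing the data. The values with disjoint libraries were computed from log2 CPM with other prior counts, so the change of sign cannot be laid on the controls alone. Of 364 values for single chromosomes, also chosen after seeing the data, 326 held and 0 turned direction, and chromosomes 6, 9, 13, 14, 15, 20 and 22 differed between the knock-downs under all 13 settings. Depth limits what can be said of genes under about 0.182 CPM, the level of 3 counts in the smallest library.

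With the replicate block, calls were 2301 in N_28, 424 in N_30, 616 in the mean, 3673 between the knock-downs, 74 in the same and 156 in opposite directions, and 6 lists were called in the mean. The block kept 1535 of 1538, 130 of 130, 268 of 268 and 2750 of 2755 calls. Pairs of libraries with the same number correlated between -0.0588 and 0.306 in their deviations, with 5 of 9 pairs over 0.1, and 7 of 9 libraries correlated best with one of their own number, and the second principal component set library 3 of each group apart (10.9 to 19.1, the others at 2.85 or below), a sign in the data, not the labels, of effects shared by libraries of one number, clearest between control and N_30, where all 3 pairs were over 0.1. Among the genes named by rank, the lists and the chromosomes called, the block ended the call of chromosome 15 in N_30 (adjusted p = 0.0517) and no other.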

Other observations

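All tests of the liver gene levels were chosen after the result had been seen, except that on the mouse alignment.

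Lists beyond those of mitochondria, stress and liver also held calls. Of 29 interferon response genes, 4 rose and 2 fell in N_28 (5 and 4 adjusted over the list alone), with IRF1 at 0.59 and OAS3 at 0.61, and 1 rose and 2 fell in N_30 (7 and 2 adjusted over the list alone), IFITM3 (0.39), HERC5 (-1.35) and OAS1 (-0.79). IFITM3 has a near-identical paralog. Of 17 epithelial junction genes, 1 rose and 4 fell in N_28 (1 and 4 adjusted over the list alone), with the keratin KRT7 at -0.41, and DSP (-0.55) fell in N_30 (4 rose and 1 fell adjusted over the list alone). Of 31 apoptosis regulators, the inhibitor BIRC2 (0.66) rose and BCL2L11 (-0.40), BCL2 (-0.56) and BMF (-0.72) fell in N_28 (3 and 4 adjusted over the list alone), and 0 passed in N_30 under both adjustments. The light chain gene MAP1LC3A, a marker of autophagosomes, fell in N_28 (-1.41) and did not pass in N_30 (0.69). TOP2A (-0.50) was the 1 of 40 G2/M and mitosis genes to fall in N_28, with 0 adjusted over the list alone and 0 in N_30.

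Some genes outside the mature liver set were well detected. Of 14 genes of a list of HEK293 and neural markers, 7 had a control mean of at least 1 CPM, with a median of 0.809 CPM. In control libraries its members PAX2 stood at 154 ± 35.1 CPM, ENO2 at 104 ± 9.01 CPM and LHX1 at 99.2 ± 4.22 CPM (n = 3). The keratin KRT7 stood at 656 ± 57.6 CPM and the collagen COL6A3 at 1818 ± 144 CPM (n = 3). PAX2, ENO2 and COL6A3 were named after their values were seen. LHX1 fell in N_28 (-0.90). The 17 haematopoietic markers had a median of 0 CPM and only CD14 was tested (-0.52 in N_28, not passing).

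Several liver marker genes were near 0 in libraries labelled Huh7, with a highest level of 1.31 CPM among ALB, AFP, APOA1, APOB, APOH and TTR. A cell line other than the one on the labels is a candidate explanation. It would give such levels, but they are the flagged pattern itself and so no separate test of that explanation. The OPA1 knock-down is not the cause, since the highest control value of these genes was 0.929 CPM. Alignment to the mouse build is not either, since 1916 human pseudogene and long non-coding rows were among the tested genes. A dedifferentiated culture of the labelled line, in which HNF4A reached at most 0.181 CPM, cannot be told apart from another line, because no genotype was analysed here.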
